A study of Mus musculus with 6 samples.

How the data were processed

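Gene expression was measured by RNA sequencing in 6 libraries of bone marrow-derived macrophages, with 2 libraries in each of 3 genotypes. The genotypes were wild type (WT), Ch25h knockout (Ch25hKO) and a knockout of both liver X receptor genes (LXRdKO). Bone marrow was cultured with M-CSF until day 7 and stimulated with LPS at 100 ng/ml for 8 h, per the labels' protocols. RNA was amplified to cDNA with an Ovation kit before library construction, per the labels' protocols, and sequenced on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles.

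The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and no normalization. CASAVA, STAR 2.3.0, HTSeq and the mouse genome mm10 are named in the submitters' processing notes, and alignment of quality-filtered reads with STAR is stated in the series' design text. The gene annotation, the counting mode and any strand setting are not given in the sources used here. Reads of overlapping or antisense genes may therefore be assigned to either gene. The same holds for near-identical copies, so values of Pira2, Pilrb2, Serpina3f, Serpina3g, Tgtp1, Entpd4, Erdr1, the Klk1b genes and Mid1, which overlaps another annotated transcript, are uncertain. Amplification before sequencing means that reads are not independent molecules, so the counting intervals given for low counts cover counting error only.

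The table held 23337 gene symbols, of which 5683 had no count in any library. Total counts ranged from 41650513 to 45872964 per library. edgeR 4.0.16 in R 4.3.3 was used for the main test. Genes were kept with edgeR's filterByExpr at its default settings, which left 12923 genes holding 99.98% of the counts. Libraries were scaled by TMM, and a negative binomial model with 1 mean per genotype was fitted to all 6 libraries with robust quasi-likelihood dispersions, so that the 3 groups shared 1 estimate of the spread. This left 3 residual degrees of freedom, to which the empirical Bayes step added 14.4. The common biological coefficient of variation was 4.41%. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. Expression in CPM, counts scaled to a common library size, was computed with TMM-scaled library sizes.

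Before the data were examined, the main test, the alternatives, 24 gene lists and the rule for the genes to be named were fixed. The lists covered cholesterol synthesis, fatty acid synthesis, LXR targets, the oxysterol pathway, the IL-1 family and inflammasome, inflammatory cytokines, chemokines, the interferon response, endoplasmic reticulum (ER) stress, alternative activation, MHC class II presentation, phagocytosis and clearance, lysosome, hypoxia and glycolysis, and cell cycle. Further lists held markers of macrophages, neutrophils, dendritic cells, B cells, T and NK cells, mast cells and basophils, erythroid cells and megakaryocytes, and stromal cells, and transcripts of the mitochondrial genome. Lists overlap in part: Scd1 and Scd2 are in both the fatty acid and the LXR target lists, Mertk is in the LXR target and clearance lists, Stab1 is in the clearance and alternative activation lists, and Lcn2 is in the cytokine and neutrophil lists.

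The rule named, in each comparison, the 3 targeted genes, 10 genes fixed in advance (among them Il1b, Abca1, Abcg1, Srebf1, Hmgcs1, Insig1, Idi1 and Sqle), the 10 called genes with the largest increase and the 10 with the largest decrease, and the 4 members of each list with the lowest p. The genes of largest change had a mean of at least 5 CPM and no overlap between the libraries of both groups, and predicted or unnamed gene models were left out. The values of some genes that the rule selects are not reported here, and all members of each list stay in its counts and tests. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, two-sided, with adjustment over the 20 lists that qualified. Camera was repeated with an estimated correlation, which rests on 3 residual degrees of freedom here, and the lists were also tested with fry, which asks whether the genes of a list move in 1 direction without comparing them with other genes.

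The alternatives were RLE and upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 5 CPM in at least 2 libraries, a fit of only the libraries compared, the replicate number as a block, and each library left out in turn. Leaving out a library leaves a group with 1 library, which was then assumed to vary like the other groups. Fits without a library and fits of only the libraries compared kept the genes of the main filter. A block with crossed replicate numbers was added after the data were seen. Both knockouts were compared with the same WT libraries. For the covariance, correlation and shared calls without effects, 100 simulations of unchanged groups were run. Counts of all 6 libraries, WT included, were drawn from the WT means and the spread estimated over the 3 groups together.

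The gene test was tested on simulated data for Ch25hKO against WT, with counts drawn for the 12923 genes from the real means and library sizes and 50 genes changed at each fold. It recovered 48% of genes changed 1.25-fold, 68% at 1.5-fold, 78% at 2-fold and 100% at 4-fold, and called 13 of the unchanged genes. A smaller share of genes was changed there than the 39.3% called in the data, so these rates may not carry over. In the simulated comparison of LXRdKO with WT, which held no changed gene, it called 0 genes, and both DESeq2 and limma-voom called 1. A simulated list of 25 genes changed 1.5-fold was called by camera with the preset and the estimated correlation, and 0 of 19 unchanged lists were called with either. Simulated genes were drawn independently, so this does not test false calls of lists whose genes vary together. The interferon list, for example, had an estimated correlation of 0.522 in Ch25hKO against WT.

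Gene positions were taken from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10. A position was found for 12760 of the 12923 tested genes (98.7%), 1111 of them through an older symbol. Positions, taken at gene midpoints, were compared with changes in windows of 5 Mb on each side of each targeted gene, against other windows of as many genes. Figures were drawn with matplotlib 3.10.9.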

Results

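Transcripts were measured in bone marrow-derived macrophages, cells grown from mouse bone marrow with the growth factor M-CSF, after 8 h with 100 ng/ml LPS, a bacterial cell wall component that activates macrophages. Wild-type cells (WT) were compared with cells lacking Ch25h (Ch25hKO) and with cells lacking both liver X receptors, LXRα and LXRβ (LXRdKO). The strain of all samples was given as C57BL/6. Ch25h encodes cholesterol 25-hydroxylase, which makes 25-hydroxycholesterol, an oxysterol known to hold back the sterol-responsive transcription factor SREBP2 and to act as an LXR ligand. All libraries came from stimulated cells, so no value gives the response to LPS itself.

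Each group had 2 libraries. Total counts were 45343311 and 42816660 in WT, 41650513 and 42855130 in Ch25hKO, and 44576055 and 45872964 in LXRdKO. The 10 most abundant genes took 11.6% to 12.2% of the counts in every library. The ribosomal RNA precursor Rn45s took 1.01% and 1.06% of the counts in the LXRdKO libraries and 1.26% to 1.30% in the other 4. The nuclear RNA Malat1 took 1.10% and 1.48% in WT, 1.79% and 1.44% in Ch25hKO, and 1.36% and 1.45% in LXRdKO, with the lowest share in WT replicate 1 and the highest in Ch25hKO replicate 1. Ribosomal protein genes took a larger share in both Ch25hKO libraries than in the other 4. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 12.4 in WT, 5.19 in Ch25hKO and 4.30 in LXRdKO. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Expression is given in CPM, counts scaled to the size of each library. Unless another error is named, values are log2 fold changes ± standard error with n = 2 libraries per group, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12923 genes.

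The targeted genes were read first. Ch25h (ENSMUSG00000050370.5, chromosome 19, 34473778 to 34475164, GRCm38) had 3120 and 3076 counts in WT and 42 and 57 in Ch25hKO, or 1.61% of the WT level. In LXRdKO it had 2509 and 2763 counts, 84.9% of the WT level. Nr1h3, which encodes LXRα (ENSMUSG00000002108.10, chromosome 2, 91184061 to 91202834), had 710 and 756 counts in WT, 806 and 859 in Ch25hKO, and 42 and 41 in LXRdKO, which left 5.65% of the WT level. Nr1h2, which encodes LXRβ (ENSMUSG00000060601.13, chromosome 7, 44549616 to 44553951), had 1292 and 1401 counts in WT, 1408 and 1507 in Ch25hKO, and 35 and 35 in LXRdKO, which left 2.59% of the WT level. Which part of each gene was deleted is not given in the sources used here. Each knockout library was therefore low in the genes its label names. In LXRdKO, Ch25h fell by 0.24 ± 0.06 (edgeR adjusted p = 0.00566), a call that was lost without LXRdKO replicate 1 (-0.17, edgeR adjusted p = 0.129). In Ch25hKO, Nr1h3 (0.20 ± 0.08, edgeR adjusted p = 0.0536) and Nr1h2 (0.13 ± 0.07, edgeR adjusted p = 0.144) did not pass the test, and both passed it without WT replicate 2 (0.25 and 0.19).

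**Figure D1:**
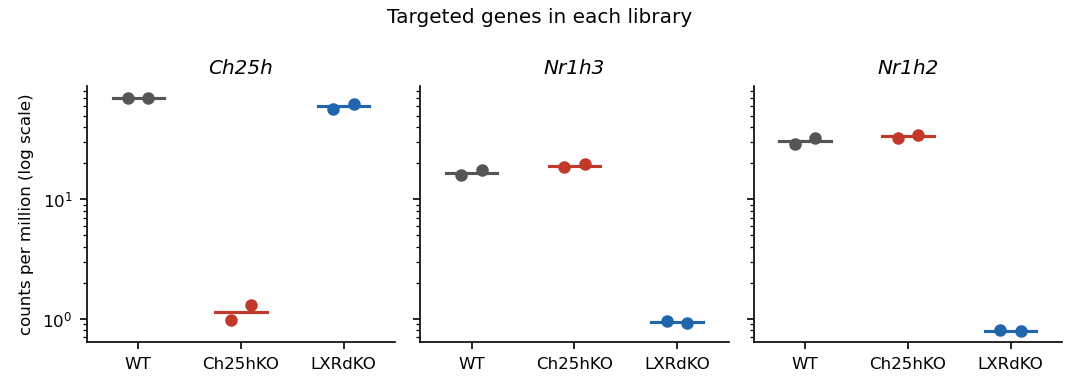
CPM of the 3 targeted genes on a log scale, with 1 point per library and a line at the mean of each group of 2. Ch25h was at 1.14 CPM in Ch25hKO against 70.5 in WT, and in LXRdKO Nr1h3 was at 0.942 against 16.7 and Nr1h2 at 0.795 against 30.7.

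Without Ch25h, genes of cholesterol synthesis rose steeply. The 25 tested members of the list comprise the enzymes from acetyl-CoA to cholesterol and other SREBP2 targets, and 23 of them rose, 0 fell and 2 did not pass the test. Hsd17b7, an enzyme of late sterol synthesis, rose 30.3-fold, from 3.86 ± 0.0509 to 117 ± 0.853 CPM (SD, n = 2). Sqle, which encodes squalene epoxidase, rose 26.0-fold, and Idi1, an isomerase of the isoprenoid steps, rose 21.2-fold. Hmgcs1, an early enzyme of the pathway, rose 13.8-fold, from 16.6 ± 1.07 to 228 ± 1.49 CPM (SD, n = 2).

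The log2 fold changes of this group were 4.92 ± 0.07 for Hsd17b7, 4.70 ± 0.08 for Sqle and 4.41 ± 0.10 for Idi1. Stard4, a cholesterol carrier, was at 4.39 ± 0.13. The pathway enzymes were Cyp51 (4.14 ± 0.07), Fdps (4.06 ± 0.07), Fdft1 (3.80 ± 0.07), Hmgcs1 (3.78 ± 0.06) and Sc4mol (3.74 ± 0.06). Along with Erdr1, Stard4 and these enzymes made up the rest of the largest increases under the naming rule. Insig1, which holds SREBPs in the ER, rose 6.07-fold. The median over the list was 2.82. Adjusted over the list alone, 23 members also rose. The list was called by camera, and it was the only one of 20 in this comparison whose call held with an estimated correlation (adjusted p = 0.000521 with an estimated correlation). Genes of fatty acid synthesis rose with it: 11 of 14 rose, 0 fell and 13 rose when adjusted over the list alone. Fasn, the fatty acid synthase, rose by 3.12 ± 0.08, the desaturase genes Scd2 and Fads1 by 1.56 ± 0.07 and 1.34 ± 0.07, and the acyl-CoA synthetase gene Acsl3 by 1.71 ± 0.10. Camera called the list (mean 1.28, adjusted p = 1.68e-24), with an adjusted p = 0.124 with an estimated correlation.

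Genes regulated by LXR moved both ways in Ch25hKO. Of 16 tested members of the LXR target list, 7 rose, 7 fell and 2 did not pass. The cholesterol exporter genes Abcg1 and Abca1 fell 6.08-fold and 1.42-fold (-2.60 ± 0.07 and -0.51 ± 0.05). Mylip, which encodes a ubiquitin ligase, fell 2.66-fold (-1.41 ± 0.06), and the small GTPase gene Arl4c fell 3.59-fold (-1.84 ± 0.11). Srebf1, which encodes SREBP1, rose 1.72-fold (0.79 ± 0.08). Adjusted over the list alone, 7 rose and 8 fell, and camera did not call the list (adjusted p = 0.0834). In the oxysterol list, camera called a decrease (adjusted p = 0.000215, and adjusted p = 0.257 with an estimated correlation) that rests on Ch25h, at -5.95 ± 0.10. The mean of its 7 members was -0.80, their median lay near 0, from -0.09 without Ch25hKO replicate 2 to 0.08 without Ch25hKO replicate 1, and 2 of the other 6 rose, among them the bile acid enzyme gene Hsd3b7 (0.35 ± 0.08, a call lost without Ch25hKO replicate 2, edgeR adjusted p = 0.0537), and 2 rose and 1 fell when adjusted over the list alone. The number that rose came to 0 without Ch25hKO replicate 2 and to 1 without WT replicate 2 or Ch25hKO replicate 1. The call of the list was lost with limma-voom and without a low-count filter.

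Most interferon-stimulated genes tested fell without Ch25h. Of 36 tested members, 31 fell, 0 rose and 5 did not pass, and 32 fell when adjusted over the list alone. Cmpk2, which encodes a nucleotide kinase, fell 2.79-fold, from 2743 ± 281 to 985 ± 121 CPM (SD, n = 2). The interferon-stimulated genes Ifit2, Mx2 and Oasl1 fell by 1.19 ± 0.08, 0.94 ± 0.06 and 0.75 ± 0.06 on the log2 scale. The midpoint of Ifit2 lies 89.1 kb from that of Ch25h on chromosome 19. Camera called the list (median -0.39, adjusted p = 1.53e-17), with an adjusted p = 0.318 with an estimated correlation.

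Inflammatory genes moved in both directions in Ch25hKO. Il1b, the gene of interleukin-1β, rose by 0.59 ± 0.06 on the log2 scale, from 2674 ± 99.5 to 4021 ± 14.9 CPM (SD, n = 2). Of 18 members of the IL-1 and inflammasome list, 3 rose and 6 fell, with the DNA sensor gene Aim2 at -0.60 ± 0.06, the ATP receptor gene P2rx7 at -0.59 ± 0.06 and Casp1 at -0.39 ± 0.06. Camera did not call this list (adjusted p = 0.375), and 3 rose and 6 fell when adjusted over the list alone. Of 21 inflammatory cytokines and enzymes, 7 rose and 10 fell, including Tnfsf9 (0.69 ± 0.06), the scavenger receptor gene Marco (0.86 ± 0.07), Osm (-1.50 ± 0.09) and the anti-inflammatory cytokine gene Il10 (-0.94 ± 0.07). This list was not called either (adjusted p = 0.654), and 8 rose and 10 fell when adjusted over the list alone. Of 20 chemokines, 4 rose and 10 fell, and 5 rose and 10 fell when adjusted over the list alone. The monocyte attractant genes Ccl2 and Ccl7 fell 2.31-fold and 2.01-fold, and the interferon-inducible Cxcl11 and Cxcl10 fell 1.99-fold and 1.77-fold. Camera called the chemokines lower (median -0.22, adjusted p = 0.00135, and adjusted p = 0.343 with an estimated correlation), a call that was lost without a low-count filter.

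Stress and metabolic genes also moved in Ch25hKO. Of 20 ER and integrated stress genes, 17 fell and 1 rose, with the transcription factor genes Ddit3 and Atf3 at -0.93 ± 0.08 and -0.54 ± 0.06 and the chaperone gene Hspa5 at -0.45 ± 0.07. Camera called the list (median -0.24, adjusted p = 0.000255, and adjusted p = 0.343 with an estimated correlation), and the same counts were found when adjusted over the list alone, but 8 fell without Ch25hKO replicate 1, and 0 rose without WT replicate 2 or any 1 of the 4 knockout libraries. Of 20 glycolytic and hypoxia-regulated genes, 13 rose and 2 fell, with the oxygen sensor gene Egln3 at 0.75 ± 0.06, the lactate exporter gene Slc16a3 at 0.47 ± 0.05, Ero1l at 0.67 ± 0.06 and the growth factor gene Vegfa at -0.57 ± 0.06. Adjusted over the list alone, 13 rose and 3 fell, and camera called the list (median 0.21, adjusted p = 0.00159, and adjusted p = 0.318 with an estimated correlation). Camera called none of 5 further lists, with adjusted p-values of 0.0848 for alternative activation (5 of 12 rose and 2 fell), 0.767 for MHC class II (4 of 13 rose and 3 fell), 0.201 for clearance (4 of 18 rose and 9 fell), 0.201 for lysosome (8 of 20 fell) and 0.375 for cell cycle (2 of 24 rose and 6 fell). The same counts were found for these 5 when adjusted over the list alone, except that 1 lysosomal gene rose. The fall of lysosomal genes came to 2 without Ch25hKO replicate 1 and to 4 without Ch25hKO replicate 2, LXRdKO replicate 1 or LXRdKO replicate 2. Falling alternative activation genes came to 0 without Ch25hKO replicate 1 and to 1 without WT replicate 1, and 1 cell cycle gene rose without Ch25hKO replicate 1. Without WT replicate 1, 2 lysosomal genes rose. With a filter of at least 5 CPM, which left 7 cell cycle and 5 alternative activation genes, 2 cell cycle genes fell and 0 alternative activation genes fell while 3 rose. Examples were the mannose receptor gene Mrc1 (0.78 ± 0.06), Arg1 (1.03 ± 0.08), the costimulatory gene Cd86 (-0.74 ± 0.06) and the lipoprotein receptor gene Scarb1 (2.38-fold higher). Others were the lysosomal lipase gene Lipa (-0.49 ± 0.05), whose midpoint lies 35.4 kb from that of Ch25h, and the proliferation marker Mki67 (0.82 ± 0.07). The median of the alternative activation list was -0.16 although its mean and test pointed up, and the MHC class II and cytokine lists had medians above 0 with means and tests pointing down.

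Markers of other cells were read beside these groups. Of 10 dendritic cell markers, 4 fell and 0 rose, among them Xcr1 (-1.51 ± 0.10) and Ccr7 (-0.79 ± 0.11), and of 10 stromal markers 6 rose and 1 fell, among them Pdgfrb (1.32 ± 0.10) and Col1a2 (1.59 ± 0.21), which stood at 12.6 and 4.19 CPM in Ch25hKO. Counts were the same when adjusted over the list alone, and with a filter of at least 5 CPM, which left 2 and 3 members, 2 dendritic cell markers fell and 2 stromal markers rose. Camera called both lists, with adjusted p-values of 0.0474 and 0.0327 (adjusted p = 0.343 and adjusted p = 0.318 with an estimated correlation). The dendritic cell call was lost in 6 of 14 alternatives, including without WT replicate 1, WT replicate 2 or Ch25hKO replicate 1 (adjusted p = 0.0517, 0.0864 and 0.0703), and the stromal call in 4 of 15, including without WT replicate 2 (adjusted p = 0.0765). The adjusted p ranged from 0.0340 to 0.0878 for dendritic cells and from 0.0106 to 0.283 for stromal cells over the alternatives. Camera did not call macrophage (adjusted p = 0.651, 1 of 11 rose and 2 fell), neutrophil (adjusted p = 0.201, 3 of 7 rose) or erythroid and megakaryocyte markers (adjusted p = 0.659, 1 of 4 fell), with the same counts when adjusted over the list alone, and 4 macrophage markers fell without WT replicate 2. Without Ch25hKO replicate 1, 0 macrophage markers rose and 1 fell, and 0 erythroid and megakaryocyte markers fell, and 2 macrophage markers rose without WT replicate 1. Lists of B cells, T and NK cells, and mast cells and basophils had 2, 1 and 2 tested members and were not tested as lists. In Ch25hKO, the B cell markers Ms4a1 and Cd79b were at -1.21 ± 0.51 and -0.38 ± 0.41 and did not pass, and adjusted over the list alone 0 passed. Ms4a1 passed with limma-voom and without Ch25hKO replicate 1 (adjusted p = 0.0315 and 0.0112), and stood at -2.68 without Ch25hKO replicate 1 and -0.49 without Ch25hKO replicate 2. The T cell gene Lck fell (-0.64 ± 0.21, edgeR adjusted p = 0.0220), a call lost with DESeq2 and without WT replicate 1 or Ch25hKO replicate 2 (-0.36 and -0.41 without these). Hdc and Gata2 of the mast cell list fell (-0.39 ± 0.06 and -0.96 ± 0.27), and the call of Gata2 was lost with DESeq2 and without Ch25hKO replicate 1 (adjusted p = 0.0716 without that library). Counts of the T cell and mast cell lists were the same when adjusted over the list alone. The table held 0 of the 13 mitochondrial transcripts.

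Across all tested genes, 2557 were higher and 2516 lower in Ch25hKO than in WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among these, 194 were at least 2-fold higher and 413 at least 2-fold lower, and the median size of a called change was 0.40 on the log2 scale. Under the naming rule, the largest increase was that of Erdr1, with 750 counts over the Ch25hKO libraries and 4 over the WT libraries. This is a ratio of 189 (95% counting interval 73.7 to 697). The rule requires a mean of at least 5 CPM and leaves out predicted or unnamed models. By it, the largest decreases after Ch25h and Abcg1 were those of Uaca (-2.01 ± 0.11), Serpinb6b (3.99-fold), the cyclin gene Ccnd1 (-1.85 ± 0.08) and Serpina3g (-1.85 ± 0.09). Arl4c, Cytip (-1.72 ± 0.09), Serpina3f (-1.67 ± 0.15) and Igsf9 (-1.60 ± 0.12) followed. Outside it, Cyp26a1 (-2.42 ± 0.57) and Gp9 (-2.35 ± 0.59) fell more than Uaca. Without Ch25hKO replicate 1, 1501 genes were higher. With a filter of at least 5 CPM, 68 and 130 were at least 2-fold higher and lower.

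**Figure D2:**
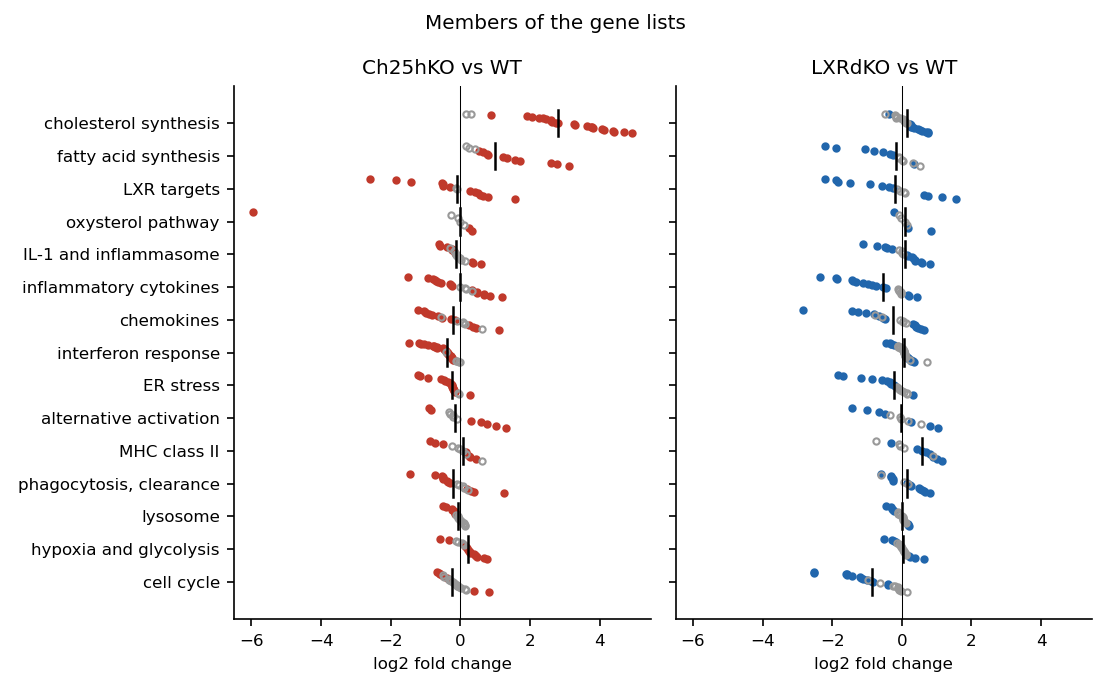
Log2 fold changes of every tested member of 15 gene lists in Ch25hKO (left) and LXRdKO (right) against WT, with filled points for members that passed edgeR's test, open points for those that did not and a bar at each list's median. The median of the cholesterol synthesis list was 2.82 in Ch25hKO and 0.15 in LXRdKO, and that of the inflammatory cytokine list was -0.53 in LXRdKO.

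Without the LXRs, the steep rise of sterol synthesis was not seen. Cholesterol synthesis genes had a median log2 fold change of 0.15, with 12 of 25 members higher and 1 lower, among them Srebf2, the gene of SREBP2, which rose 1.62-fold. Without LXRdKO replicate 2, 5 of them were higher, and 0 were lower without LXRdKO replicate 1 and 2 without WT replicate 2. Of 21 inflammatory cytokines and enzymes, 12 fell and 3 rose (1 without LXRdKO replicate 1 or LXRdKO replicate 2). Camera called this list lower (adjusted p = 4.76e-18), a call that was lost with an estimated correlation (adjusted p = 0.103 with an estimated correlation). Il12b, a subunit gene of interleukin-12, fell 3.69-fold, from 26.7 ± 1.63 to 7.23 ± 0.278 CPM (SD, n = 2), and the neutrophil growth factor gene Csf3 fell 3.61-fold. Cxcl1, a neutrophil attractant gene, fell 7.21-fold, from 78.4 ± 2.64 to 10.9 ± 1.10 CPM (SD, n = 2).

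The sterol genes Srebf2 (0.70 ± 0.07), Sc4mol (0.52 ± 0.07), Sqle (0.48 ± 0.10), Idi1 (0.59 ± 0.14) and Hmgcs1 (0.26 ± 0.07) rose, the last with a call lost without WT replicate 2 or LXRdKO replicate 2 (edgeR adjusted p = 0.0619 and 0.0743, over alternatives 0.000764 to 0.0743). Sqle stood at 0.31 without WT replicate 1. Insig1 (0.10 ± 0.06, edgeR adjusted p = 0.236) did not pass. Camera called the cholesterol list (adjusted p = 0.0102, and adjusted p = 0.205 with an estimated correlation), and 12 rose and 1 fell when adjusted over the list alone, but 5 rose without LXRdKO replicate 2, and 0 fell without LXRdKO replicate 1 and 2 without WT replicate 2. Of 14 fatty acid synthesis genes, 7 fell and 1 rose, with the same counts when adjusted over the list alone. The desaturase genes Scd2 and Scd1 fell by 2.19 ± 0.08 and 1.89 ± 0.13 on the log2 scale, and Acsl3 by 0.81 ± 0.12. Camera called this list (median -0.17, adjusted p = 0.000222, and adjusted p = 0.295 with an estimated correlation), with a median of -0.32 under a filter of at least 5 CPM.

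Of 16 LXR targets, 8 fell and 4 rose in LXRdKO, and 9 fell and 4 rose when adjusted over the list alone. Those that fell included Mylip (-1.85 ± 0.06), Abcg1 (-0.91 ± 0.06), Scd2 and Scd1. The apolipoprotein genes Apoc2 and Apoe rose 2.94-fold and 2.21-fold, Apoe from 620 ± 38.6 to 1371 ± 9.46 CPM (SD, n = 2), and Mertk, a receptor for dying cells, rose by 0.65 ± 0.06. Srebf1 (0.11 ± 0.08, edgeR adjusted p = 0.330; 0.0026 without WT replicate 1 and 0.20 without WT replicate 2) and Abca1 (-0.13 ± 0.05, edgeR adjusted p = 0.0673) did not pass, although Abca1 passed in 5 of 15 alternatives, with an edgeR, DESeq2 or limma adjusted p between 0.0151 and 0.297. Camera called the list lower (median -0.19, adjusted p = 0.00477, and adjusted p = 0.205 with an estimated correlation), a call that was lost with limma-voom and without a low-count filter. The oxysterol list was not called (adjusted p = 0.526), with Cyp27a1, which encodes sterol 27-hydroxylase, at 0.83 ± 0.14, and 2 rose and 1 fell both over all genes and adjusted over the list alone. In this list 1 rose without WT replicate 2, Ch25hKO replicate 1, LXRdKO replicate 1 or LXRdKO replicate 2, and 0 fell without LXRdKO replicate 1.

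Among inflammatory genes in LXRdKO, Csf3 (-1.85 ± 0.11), Il12b (-1.88 ± 0.09), Il10 (-1.30 ± 0.07) and the prostaglandin synthase gene Ptgs2 (-1.10 ± 0.06) fell. Camera called the cytokine list (median -0.53, adjusted p = 4.76e-18, and adjusted p = 0.103 with an estimated correlation), with 12 fallen and 3 risen also when adjusted over the list alone, and 1 risen without LXRdKO replicate 1 or LXRdKO replicate 2. Of 20 chemokines, 8 fell and 6 rose (9 fell and 6 rose when adjusted over the list alone), with Cxcl1 at -2.85 ± 0.07, Ccl22 at -1.43 ± 0.06, Ccl2 at -1.03 ± 0.07 and Cxcl2 at -0.78 ± 0.07. Camera called them lower (median -0.26, adjusted p = 7.85e-05, and adjusted p = 0.282 with an estimated correlation), a call that was lost with limma-voom and without a low-count filter. The median of the chemokines was -0.04 without that filter and -0.08 with a filter of at least 5 CPM. Of 18 IL-1 and inflammasome genes, 9 rose and 5 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.804). Il1a fell by 0.72 ± 0.06 on the log2 scale, the transcriptional regulator gene Nfkbiz by 1.12 ± 0.06, and the inflammasome adaptor gene Pycard rose by 0.81 ± 0.06. Without LXRdKO replicate 2, 5 of these genes rose. Il1b stood at 0.16 ± 0.06, and its call (edgeR adjusted p = 0.0486) was lost in 9 of 15 alternatives, among them without WT replicate 1, either Ch25hKO replicate or either LXRdKO replicate, with adjusted p-values from 0.00826 to 0.259 over all of them. Interferon-stimulated genes were not called (adjusted p = 0.480), with 8 of 36 higher and 5 lower, and 9 and 5 when adjusted over the list alone. Those counts moved to between 3 and 11 higher and between 2 and 9 lower with single libraries left out. There were 3 higher without LXRdKO replicate 2 and 4 without WT replicate 2, Ch25hKO replicate 1 or LXRdKO replicate 1, and 9 lower without WT replicate 2, 3 without WT replicate 1 and 2 without LXRdKO replicate 1.

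Antigen presentation genes were read next in LXRdKO. Of 13 MHC class II and costimulatory genes, 7 rose and 1 fell, also when adjusted over the list alone, and 2 fell without WT replicate 2. Cd74, the invariant chain gene, rose 2.23-fold (1.16 ± 0.06), and the class II genes H2-Ab1, H2-Aa and H2-Eb1 rose by 1.02 ± 0.05, 0.89 ± 0.05 and 0.82 ± 0.06. Camera called the list (median 0.57, adjusted p = 2.07e-08, and adjusted p = 0.205 with an estimated correlation). Of 24 cell cycle genes, 14 fell and 0 rose, and 16 fell when adjusted over the list alone, with the cyclin genes Ccnb2 and Ccnb1 at -2.53 ± 0.17 and -2.52 ± 0.22 and the topoisomerase gene Top2a at -1.58 ± 0.12. Camera called this list (median -0.86, adjusted p = 1.99e-07, and adjusted p = 0.103 with an estimated correlation). Most of these genes were low, with Ccnb1 at 2.87 CPM and Top2a at 9.33 CPM in WT, and with a filter of at least 5 CPM 7 were left, of which 3 fell, with a median of -0.15 (camera adjusted p = 0.0244). The more abundant Mki67 (-0.11 ± 0.07) and Pcna (-0.09 ± 0.06) did not pass. Of 20 stress genes, 11 fell and 1 rose (12 and 2 when adjusted over the list alone), with Trib3 at -1.70 ± 0.19, Ddit4 at -1.18 ± 0.12 and the asparagine synthetase gene Asns at -0.84 ± 0.09. Camera called them lower (median -0.21, adjusted p = 0.000370, and adjusted p = 0.386 with an estimated correlation), with a median of -0.12 without WT replicate 1, and 0 rose without LXRdKO replicate 2 and 2 without WT replicate 1. Without WT replicate 1, 1 cell cycle gene rose.

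Of 18 clearance genes, 9 rose and 6 fell in LXRdKO (10 and 6 when adjusted over the list alone), among them the complement genes C1qc (0.68 ± 0.06) and C1qb (0.57 ± 0.06) and the scavenger receptor gene Cd36 (-0.60 ± 0.05). Camera called them higher (adjusted p = 0.0334, and adjusted p = 0.600 with an estimated correlation), a call lost in 5 of 15 alternatives, including without WT replicate 2 or LXRdKO replicate 2 (adjusted p = 0.187 and 0.105, over alternatives 0.00872 to 0.187), and 1 gene fell without LXRdKO replicate 1. Of 11 macrophage markers, 7 rose and 0 fell (8 rose when adjusted over the list alone). Mpeg1, which encodes a pore-forming protein, rose by 0.34 ± 0.06, the lysosomal membrane gene Cd68 by 0.31 ± 0.05 and the M-CSF receptor gene Csf1r by 0.30 ± 0.05. Camera called this list (adjusted p = 0.00138, and adjusted p = 0.382 with an estimated correlation), with 4 risen without LXRdKO replicate 1 or LXRdKO replicate 2. Of 7 neutrophil markers, 5 fell and 1 rose, also when adjusted over the list alone, with S100a8 at -1.11 ± 0.06 and Lcn2, which LPS also induces in macrophages, at -0.46 ± 0.06. Camera called this list lower (adjusted p = 0.0144, and adjusted p = 0.279 with an estimated correlation), and 3 fell without LXRdKO replicate 1 or LXRdKO replicate 2. The call was lost with limma-voom and without a low-count filter. Camera did not call dendritic cell markers (adjusted p = 0.216), alternative activation (adjusted p = 0.526), lysosome (adjusted p = 0.524), hypoxia and glycolysis (adjusted p = 0.761), erythroid (adjusted p = 0.657) or stromal markers (adjusted p = 0.761). Rising and falling genes numbered 0 and 2, 3 and 4, 3 and 5, 4 and 4, 0 and 0, and 2 and 1 in this order, and 0 and 2, 5 and 4, 3 and 5, 5 and 5, 0 and 0, and 4 and 2 when adjusted over the list alone. Without LXRdKO replicate 2, 1 alternative activation gene fell, 0 lysosomal genes rose and 2 glycolytic genes fell, and without WT replicate 2, 1 alternative activation gene fell and 5 rose, 1 lysosomal gene rose and 1 stromal marker rose. Without LXRdKO replicate 1, 2 alternative activation genes fell, 0 lysosomal genes rose and 1 stromal marker rose, and without Ch25hKO replicate 1, 1 lysosomal gene rose. Of the lists too short to test, both mast cell markers fell in LXRdKO, Hdc by 0.31 ± 0.06 and Gata2 by 1.40 ± 0.28, and of the B cell markers Cd79b fell by 1.39 ± 0.47 and Ms4a1 (-0.80 ± 0.48) did not pass. The T cell gene Lck (-0.04 ± 0.20; 0.24 without WT replicate 1 and -0.28 without WT replicate 2) did not pass, and these counts were the same when adjusted over the list alone. The call of Cd79b (edgeR adjusted p = 0.0315) was lost in 4 of 14 alternatives, among them without WT replicate 1, LXRdKO replicate 1 or LXRdKO replicate 2, with adjusted p-values from 0.0264 to 0.221. Medians and tests differed in sign for the IL-1, alternative activation and lysosome lists, at 0.10, -0.03 and 0.02.

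In LXRdKO, 2116 genes were higher and 1999 lower than in WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 98 and 374 of them by at least 2-fold. Under the naming rule, Erdr1 rose most (711 counts against 4, a ratio of 177, 95% counting interval 68.9 to 653). Pira2 (3.83 ± 0.13), Mid1 (3.78 ± 0.08), the growth factor gene Gdf3 (2.80 ± 0.13), Calhm2 (1.64 ± 0.12) and Pilrb2 (1.56 ± 0.07) came next. Apoc2 (1.56 ± 0.07), Txnip (1.56 ± 0.06), Napsa (1.53 ± 0.06) and Depdc7 (2.83-fold) followed. Outside the rule, Klk1b22 (6.09 ± 0.69) and G530011O06Rik (5.17 ± 0.07) rose more than Pira2. The midpoint of Napsa lies 27.8 kb from that of Nr1h2. Under the naming rule, the largest decreases after the targeted genes, Cxcl1 and Scd2 were those of Spred3 (-1.93 ± 0.11) and Plcxd2 (-1.92 ± 0.09). Outside it, Ccnb2 (-2.53 ± 0.17) and Ccnb1 (-2.52 ± 0.22) fell more than Spred3. The counts were 1292 higher and 1198 lower without LXRdKO replicate 1, and 1314 and 1265 without LXRdKO replicate 2. Without WT replicate 2, 148 genes were at least 2-fold higher. DESeq2 gave 64, and with a filter of at least 5 CPM 34 were higher and 77 lower by that much.

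**Figure D3:**
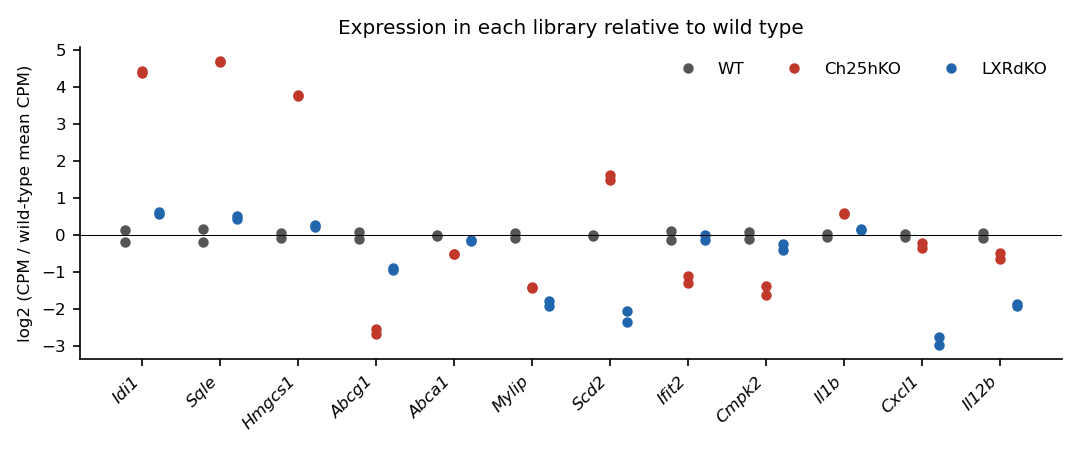
Expression of 12 named genes in each of the 6 libraries, as the log2 ratio of CPM to the mean CPM of the WT libraries, with 1 point per library. Idi1, Sqle and Hmgcs1 were highest in Ch25hKO (40.9, 130 and 228 CPM), and Scd2, Cxcl1 and Il12b were lowest in LXRdKO (12.3, 10.9 and 7.23 CPM).

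The knockouts were then compared directly, which tests the differences between their effects. Sterol synthesis separated them most: 23 of 25 cholesterol synthesis genes and 13 of 14 fatty acid synthesis genes were lower in LXRdKO than in Ch25hKO, and 0 of either were higher. Hsd17b7 differed by -4.65 ± 0.07, Sqle by -4.22 ± 0.08, Scd2 by -3.75 ± 0.08 and Fasn by -3.21 ± 0.08. All but 2 of 36 interferon-stimulated genes were higher in LXRdKO, with Ifit2 at 1.13 ± 0.08 and Ifit1 at 0.84 ± 0.07, and these 34 came to 36 when adjusted over the list alone. Of 21 cytokines and enzymes, 16 were lower and 2 higher in LXRdKO, among them Csf3 (-2.01 ± 0.11) and Il12b (-1.33 ± 0.09). Il1b was lower in LXRdKO by 0.43 ± 0.06, and Abcg1 and Abca1 were higher by 1.69 ± 0.07 and 0.38 ± 0.05.

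The test fry, which does not compare a list with other genes, called 13 lists in Ch25hKO, 11 in LXRdKO and 13 between the knockouts. Beyond camera's calls, these were LXR targets (adjusted p = 0.0146, lower), alternative activation (adjusted p = 0.00810, higher), cell cycle (adjusted p = 0.0415, lower) and neutrophil markers (adjusted p = 0.0110, higher) in Ch25hKO, dendritic cell markers (adjusted p = 0.0437, lower) in LXRdKO, and alternative activation (adjusted p = 0.0152, lower) and stromal markers (adjusted p = 0.00532, lower) in LXRdKO against Ch25hKO. It did not call clearance in LXRdKO (adjusted p = 0.0597).

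By camera, 11 of 20 lists differed between the knockouts, and only the call of cholesterol synthesis held with an estimated correlation (adjusted p = 0.000768 with an estimated correlation). The other lists lower in LXRdKO were fatty acid synthesis (median -1.31, adjusted p = 1.07e-34), inflammatory cytokines (median -0.57, adjusted p = 3.21e-10), cell cycle (median -0.59, adjusted p = 0.00188, 12 of 24 lower and 2 higher), hypoxia and glycolysis (median -0.13, adjusted p = 0.00643, 9 of 20 lower and 2 higher) and neutrophil markers (median -0.59, adjusted p = 0.00157). With an estimated correlation these had adjusted p = 0.0786, adjusted p = 0.134, adjusted p = 0.134, adjusted p = 0.260 and adjusted p = 0.171. The cell cycle call was lost with a filter of at least 5 CPM (adjusted p = 0.0999, median -0.27), which left 4 lower. The genes of the cytokine, cell cycle and hypoxia lists that were higher in LXRdKO came to 1 each without Ch25hKO replicate 1, Ch25hKO replicate 2 or LXRdKO replicate 2, and those of the cell cycle list also without LXRdKO replicate 1. Lists higher in LXRdKO were interferon-stimulated genes (median 0.42, adjusted p = 2.48e-18), MHC class II (10 of 13 higher, adjusted p = 2.52e-06), clearance (8 of 18 higher, 1 lower, and 4 lower without WT replicate 1 or WT replicate 2, adjusted p = 0.00275, median 0.27, or 0.16 with a filter of at least 5 CPM and 0.17 without a filter), macrophage markers (6 of 11 higher, adjusted p = 0.00257) and the oxysterol list (adjusted p = 1.68e-05), which again held Ch25h and lost its call with limma-voom and without a low-count filter. With an estimated correlation these had adjusted p = 0.246, adjusted p = 0.171, adjusted p = 0.402, adjusted p = 0.352 and adjusted p = 0.134. The clearance gene Mertk was higher by 1.16 ± 0.06. Adjusted over the list alone, counts were the same for cholesterol and fatty acid synthesis, cytokines, MHC class II, macrophage and neutrophil markers and the oxysterol list, while 13 cell cycle, 10 glycolytic and 2 clearance genes were lower. Lists of LXR targets (adjusted p = 0.977), chemokines (adjusted p = 0.977), ER stress (adjusted p = 0.559), lysosome (adjusted p = 0.559), dendritic cell (adjusted p = 0.484) and erythroid markers (adjusted p = 0.991) were not called, and their medians and means differed in sign. The IL-1 (adjusted p = 0.559), alternative activation (adjusted p = 0.326) and stromal lists (adjusted p = 0.0671) were not called either.

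Markers of other cells also differed between the knockouts. Of 10 stromal markers, 5 were lower in LXRdKO and 1 was higher (6 and 1 when adjusted over the list alone), among them Col1a2 (-1.53 ± 0.20), Dcn (-1.17 ± 0.12) and Pdgfrb (-0.68 ± 0.09). Of 10 dendritic cell markers, 3 were higher and 2 lower, also when adjusted over the list alone, with Xcr1 at 1.53 ± 0.10, Itgae at 1.26 ± 0.22 and Clec9a at 0.85 ± 0.16. The higher stromal marker was lost without Ch25hKO replicate 1 or LXRdKO replicate 2, and 1 dendritic cell marker was lower without Ch25hKO replicate 2 or LXRdKO replicate 2. With a filter of at least 5 CPM, 2 of 3 stromal markers were lower and 1 was higher, and 1 of 2 dendritic cell markers was higher and 1 lower. The T cell gene Lck was higher in LXRdKO (0.61 ± 0.21, edgeR adjusted p = 0.0306), a call lost with DESeq2 and without Ch25hKO replicate 2 (0.37), LXRdKO replicate 1 or LXRdKO replicate 2 (adjusted p over alternatives 0.00541 to 0.293). Of the B cell, mast cell and erythroid markers 0 passed.

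In the other lists that were not called, 10 of 18 IL-1 genes were higher and 4 lower, 7 and 6 of 16 LXR targets, 10 and 8 of 20 chemokines, 10 and 2 of 20 stress genes, 1 and 2 of 12 alternative activation genes, and 5 and 3 of 20 lysosomal genes. Adjusted over the list alone, these counts were the same except for 4 stress and 4 lysosomal genes lower. Without Ch25hKO replicate 1, 6 chemokines and 5 stress genes were higher, and 6, 5 and 5 stress genes without Ch25hKO replicate 2, LXRdKO replicate 1 and LXRdKO replicate 2. Without Ch25hKO replicate 1 or LXRdKO replicate 2, 3 lysosomal and 0 alternative activation genes were higher. Lower lysosomal genes numbered 6 without WT replicate 1 or WT replicate 2 and 1 without Ch25hKO replicate 2, LXRdKO replicate 1 or LXRdKO replicate 2. Lower alternative activation genes numbered 4 without WT replicate 1 or WT replicate 2 and 1 without Ch25hKO replicate 1, Ch25hKO replicate 2 or LXRdKO replicate 2.

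Over all genes, 2492 were higher and 2406 lower in LXRdKO than in Ch25hKO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 270 and 320 of them by at least 2-fold. The naming rule leaves out unnamed models such as G530011O06Rik. Under it, the largest differences upward besides Ch25h (5.71 ± 0.10) were those of Mid1 (2.54 ± 0.07), Ccnd1 (35.9 CPM in Ch25hKO and 144 in LXRdKO) and Uaca (1.92 ± 0.11). Gdf3 (1.84 ± 0.12), Tgtp1 (1.83 ± 0.07), Igsf9 (1.81 ± 0.12), Depdc7 (1.81 ± 0.11), Serpinb6b (1.79 ± 0.12) and Gpr65 (1.79 ± 0.07) followed. The largest downward, besides Nr1h2 (-5.39 ± 0.12) and Nr1h3 (-4.34 ± 0.12), included Idi1 (-3.81 ± 0.09), Cyp51 (-3.78 ± 0.07), Fdps (-3.75 ± 0.07) and Stard4 (-3.62 ± 0.11), sterol genes all. Without LXRdKO replicate 2 or Ch25hKO replicate 1, 1504 and 1585 genes were lower. With a filter of at least 5 CPM, 116 were higher and 117 lower by at least 2-fold.

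The overlap of both knockouts against WT was also counted. Genes higher in both numbered 906, against 418.7 for independent lists, and genes lower in both 930, against 389.2. Genes that rose in Ch25hKO and fell in LXRdKO numbered 177, against 395.5, and the reverse 293, against 412. Both comparisons use the same WT libraries, which cannot be split into sets of 2, so part of the excess may come from the shared controls. The 100 simulations of unchanged groups drew the WT libraries too, at the spread estimated over all 3 groups. A mean of 0.300 genes were called higher in both and 0.230 lower in both. Groups without effects give few calls at all, so these means do not show how much of the overlap comes from the shared controls. Genes are not independent replicates. Across them, the log2 fold changes had a covariance of 0.103, against a simulated mean of 0.0213 and a highest simulated value of 0.0242. The difference from the mean was 0.0820. The spread between the real WT libraries gives 0.0323, above that highest value. The Pearson correlation of the log2 fold changes was 0.427, against 0.496 in the simulations, and 65.4% of genes had the same sign, against 66.7%. Among genes with a mean of at least 5 CPM, those named in these comparisons that moved by at least 2-fold the same way in both were Erdr1, Pira2 and Mid1, which rose, and Serpina3g, Osm, Mylip, Plcxd2 and Ccl2, which fell.

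**Figure D4:**
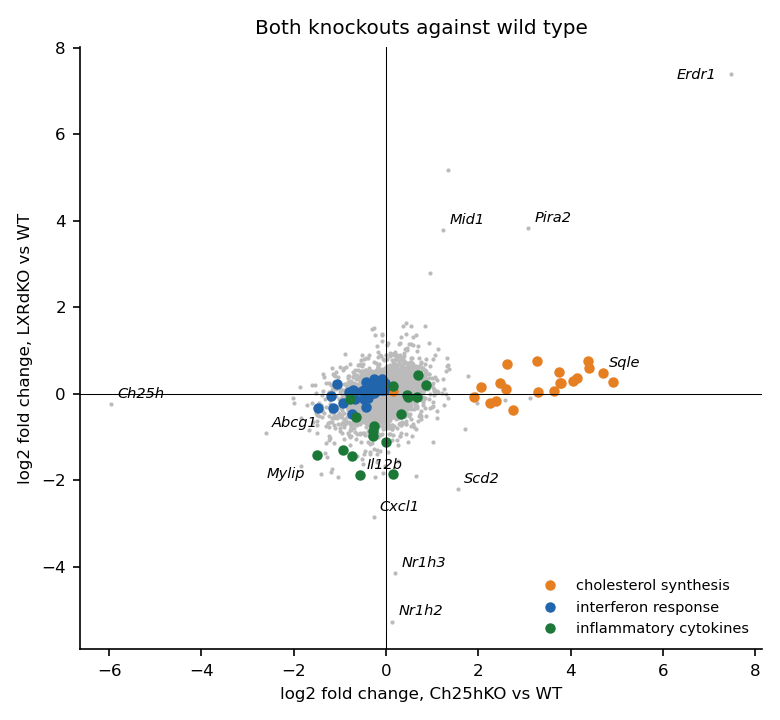
Log2 fold changes of genes with a mean of at least 5 CPM in LXRdKO (vertical) against Ch25hKO (horizontal), each against the same WT libraries, with members of 3 lists in colour. Cholesterol synthesis genes lie to the right and near 0 on the vertical axis, and interferon response genes lie to the left. Over all tested members, including any not drawn, the cholesterol synthesis median was 2.82 in Ch25hKO and 0.15 in LXRdKO. That of the interferon response was -0.39 in Ch25hKO.

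Changes near the targeted genes were counted in windows of 5 Mb on each side. Around Ch25h on chromosome 19, 22 of 58 tested genes (37.9%) were changed at least 1.5-fold in Ch25hKO, 18 of them lower, against 11.5% over the genome. Around Nr1h2 on chromosome 7, 18 of 104 genes (17.3%) were changed at least 1.5-fold in LXRdKO, 12 of them higher, against 8.39% over the genome. Of these 18, 3 are the near-identical genes Klk1b1, Klk1b11 and Klk1b22, without which 15 of 101 (14.9%) were changed. Around Nr1h3 on chromosome 2 there were 7 of 51 (13.7%) against 8.44%.

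**Figure D5:**
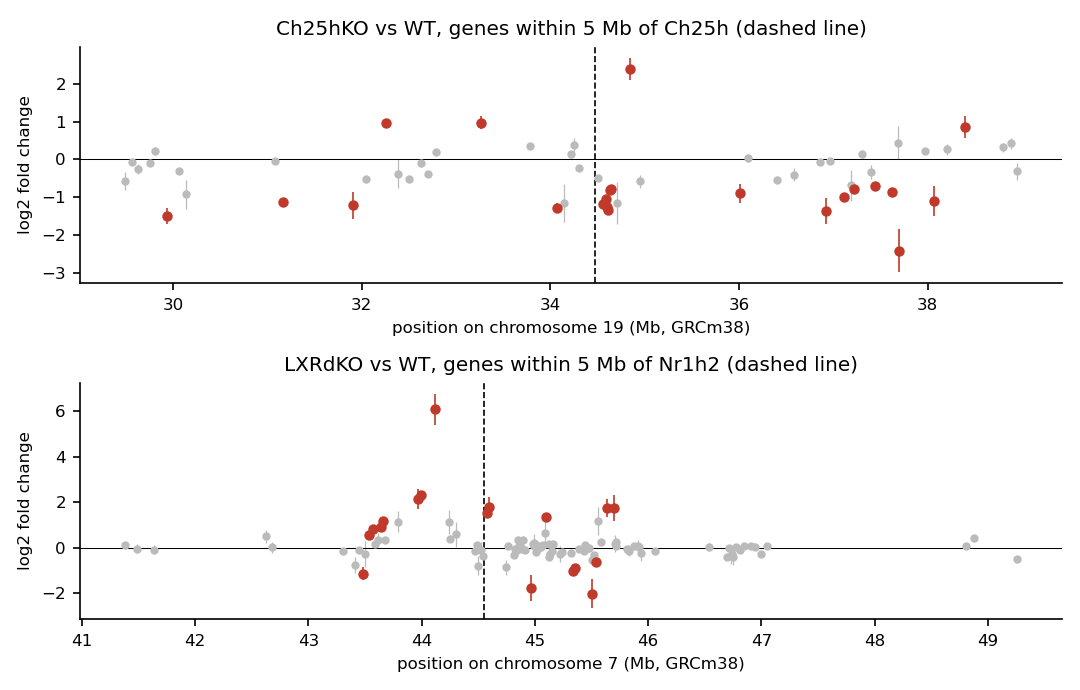
Log2 fold changes of tested genes by position (GRCm38, Mb) within 5 Mb of Ch25h in Ch25hKO (top) and of Nr1h2 in LXRdKO (bottom), with bars for the standard error, a dashed line at the targeted gene and red points for genes called and changed at least 1.5-fold. There are 22 such genes of 58 near Ch25h and 18 of 104 near Nr1h2.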

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

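The block with crossed replicate numbers and the counts of list members under each alternative were chosen after the data were seen. Of 4474 values of 302 results for named genes under the alternatives, 4387 kept the side of the threshold, 71 lost the call and 16 gained it. Direction was checked only where the main fit or the alternative made a call, and 0 of these values changed direction. For 31 called lists, 437 of 464 values kept the call and 27 lost it. Scaling moved the median of all genes by under 0.02 in each comparison.

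Counts at 2-fold depended on low genes: with the filter at 5 CPM they were 68 higher and 130 lower in Ch25hKO, 34 and 77 in LXRdKO, and 116 and 117 between the knockouts, where fewer genes were tested, and the covariance was 0.0473. DESeq2 gave 64 genes at least 2-fold higher in LXRdKO, and the cause was not tested. Lists called in LXRdKO numbered 7 with limma-voom and 7 without a low-count filter. With an estimated correlation, 1, 0 and 1 lists were called in Ch25hKO, in LXRdKO and between the knockouts. Nr1h3 in Ch25hKO passed with limma-voom (0.20), without a filter (0.21) and with the crossed block (0.20).

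With single libraries left out, values ranged as follows. In Ch25hKO, 1501 to 2478 genes were higher, Nr1h3 was at 0.14 to 0.25 and Nr1h2 at 0.0555 to 0.19. In LXRdKO, 1292 to 2097 genes were higher, 1198 to 2232 lower and 74 to 148 at least 2-fold higher, and Ch25h was at -0.30 to -0.17. Between the knockouts 1504 to 2828 were lower. These fits have fewer samples, and a lone library in a group is assumed to vary like the other groups. What else moves the counts was not tested.

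Libraries with the same replicate number did not deviate alike in WT and Ch25hKO. Correlations of the replicate differences were -0.31 for WT and Ch25hKO, -0.06 for WT and LXRdKO and 0.12 for the knockouts. The first value means that these differences ran partly in opposite order, so variation shared across groups is not excluded. Its cause was not tested. With the replicate number as a block, 2372 genes were higher and 2393 lower in Ch25hKO, 1913 and 1843 in LXRdKO, and 2365 and 2256 between the knockouts. Crossed numbers gave 2730 and 2675, 2335 and 2193, and 2651 and 2557. Depth limits genes such as Erdr1, with 4 counts in WT.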

Other observations

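Genes outside the naming rule that moved at least 2-fold the same way in both knockouts were read after their values were seen. Together with the named ones there were 5 higher and 12 lower with a mean of at least 5 CPM. Among them, the glutamate transporter gene Slc1a2 rose by 1.13 ± 0.09 in Ch25hKO and 1.04 ± 0.09 in LXRdKO. The apoptosis gene Pmaip1 fell by 1.31 ± 0.08 and 1.37 ± 0.08, the chaperone gene Hspa1a 2.29-fold and 3.48-fold, the cyclin gene Ccnf by 1.17 ± 0.10 and 1.74 ± 0.11, and Lmna, the gene of nuclear lamins A and C, by 1.13 ± 0.12 in both. The directly tested difference between the knockouts passed for Hspa1a and Ccnf (edgeR adjusted p = 0.000694 and 0.000790) and not for Slc1a2, Pmaip1 or Lmna (edgeR adjusted p = 0.476, 0.637 and 0.992). G530011O06Rik, a transcript inside the span of Mid1 (chromosome X, 169685199 to 170005736), rose by 1.34 ± 0.09 in Ch25hKO and 5.17 ± 0.07 in LXRdKO.

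The tests of substrain, sex, a divergent WT culture, chromosome 19, placement around Nr1h2, the Ifit cluster, the Klk1b genes, and noise among genes of at least 5 CPM or from the WT spread were chosen after the results were seen.

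Among effects shared by both knockouts against WT, sampling noise of the shared WT libraries is argued against as the whole cause by the covariance of 0.103, above the highest of 100 simulations (0.0242) and the 0.0323 that the spread between the WT libraries gives, and by 0.0473 among genes of at least 5 CPM (0.00619 and 0.00570). The correlation (0.427 against 0.496) and the share of equal signs (65.4% against 66.7%) lay below the simulated means. They do not argue for or against noise, since a shared control of equal size sets both near the simulated means whatever the noise level. The simulations and the WT spread measure only differences between libraries, which may be technical. A WT culture that differed by chance from both knockouts would escape them and stays open for these shared effects. A sex difference is argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose highest count in any library was 5. A substrain difference stays open: Nnt, which is disrupted in some C57BL/6 substrains, was at -0.97 ± 0.07 in Ch25hKO and -0.69 ± 0.07 in LXRdKO. Wdfy1 (-0.75 ± 0.05 and -0.97 ± 0.05), Entpd4 (3.53 ± 0.20 and 3.15 ± 0.21) and Erdr1 (7.48 ± 0.27 and 7.38 ± 0.27) each moved the same way in both. The substrain test named only Nnt, so Wdfy1, Entpd4 and Erdr1 repeat the pattern to be explained and do not test it. Values of Entpd4 and Erdr1 are also uncertain, since their reads may be shared with near-identical copies. It is a hypothesis that the WT mice may differ from both knockouts in background, and a shared effect of sterol signalling stays possible beside it.

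The lower interferon-stimulated genes in Ch25hKO were weighed next. A WT culture that differed from both knockouts is argued against by 34 of the 36 genes being higher in LXRdKO than in Ch25hKO. Changes around Ch25h on chromosome 19 are argued against as the whole cause by the 33 members elsewhere, of which 28 fell with a median of -0.36, although the 3 on chromosome 19 had a lower median of -1.05. The scaling of libraries stays open for the absolute size of the fall. The 3 scalings moved the median of all genes by under 0.02, so that their highest median for the list, -0.39, is no test of it. A scaling factor shifts all genes of a library alike, and the median of all genes was 0.0064 in Ch25hKO under TMM. The gap between the list and all genes argues against scaling as the cause of the list's place below other genes. A lower interferon response in cells without Ch25h stays a hypothesis beside a Ch25hKO culture that differed by chance, since the labels do not say how many cultures there were.

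For changed genes near the targeted loci, chance placement is argued against by the window around Ch25h in Ch25hKO, at percentile 100 of windows of as many genes, also without the Ifit cluster (percentile 100, 16 of 52 genes, a share equal to the highest other window). It stays open around Nr1h2 in LXRdKO, where the window was at percentile 97.5 but at 92.9 without the Klk1b genes, whose reads may be shared between copies, and around Nr1h3, at percentile 82. A region that varies between any cultures stays open for Ch25h, whose window was at percentile 96.1 in LXRdKO, and is argued against for Nr1h2, whose window was at percentile 41.9 in Ch25hKO. Examples chosen after their values were seen were Pank1 (2.40 ± 0.29) and Lipn (-1.28 ± 0.13) near Ch25h, and Fcgrt (1.37 ± 0.08) and Siglece (1.17 ± 0.08) near Nr1h2. Flanking sequence carried over from the strain in which an allele was made could give such clusters, a hypothesis that no sequence was read to test here.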
